A study of Homo sapiens with 80 samples.

How the data were processed

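The deposited values were used as they are: per the labels, RNA was hybridised to 2-colour Agilent arrays with Cy3 or Cy5 label, and the authors' processing notes name Agilent Feature Extraction, whose version is not given in the sources used here. Background correction and normalization steps are not given in the sources used here either. The deposited values are log2 intensities of 62976 spots for 80 samples, from 4.771 to 17.79. The 80 columns had nearly equal distributions over all spots: at one rank they differed by at most 0.08581, and their medians lay between 5.694 and 5.724. Quantile normalization was inferred from this and is not stated. Over all spots dye explained 78.6% of the first principal component of these values, against 0.175% over the named spots as bright as those tested. No further normalization was applied, and dye entered the model as a covariate. Each array carried 1 Cy3 and 1 Cy5 sample, which were treated as separate channels, and no ratio within an array was formed.

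Of the spots, 35593 carried 1 gene symbol, 0 several and 27383 (43.5%) none. Accessions of 31778 spots matched a RefSeq gene table of GRCh38.p14, which was used for names only and renamed 2023 spots; no coordinates are given. Each gene was represented by its brightest spot by mean over all samples, as 7859 genes had more than 1. The brightest 60% of the 22440 genes were tested, 13464 genes, of which the dimmest had a mean of 6.043. Technical repeats, 3 pairs, were averaged, which left 77 samples.

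Genes were tested with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading the values. The model had a term for each group of material and concentration and a dye covariate, with the array as a random block through duplicateCorrelation (correlation 0.3006). Contrasts were moderated by eBayes with trend=TRUE and robust=TRUE, with 48 residual and a median of 57.5 total degrees of freedom. Group means in the text are plain means of values adjusted for dye, while effects come from the fit, which weighs samples by the array block, so that an effect can depart from the difference of the means. Tests were 2-sided. P values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p under 0.05 was called. Concentration trends were contrasts over the control, IC5, IC10 and IC20 means, with nominal inhibition of 0, 5, 10 and 20% as the scale. Differences between materials were moderated F tests of equal effects, at IC20 and at each mass concentration given to several materials. At a p under 0.05 without adjustment chance gives 673 genes on average, 5% of those tested. As genes vary together, the count of a single comparison can lie far from this on either side by chance.

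Gene lists were fixed before the data were examined, 29 in all including 3 of markers of other cell types, and were compared with the other tested genes by limma's cameraPR with an inter-gene correlation of 0.01, adjusted over the lists of a contrast. The calls were repeated with a correlation estimated per list, and with fry, which asks whether a list moves one way on balance and does not compare it with other genes. Members were also adjusted over the list alone.

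Named genes followed a rule set in advance. For the mean response these were the 10 largest rises and the 10 largest falls past the test. For each material at IC20 they were the 6 largest rises and 6 largest falls past it with every IC20 sample on the same side of both controls, or, where there were none, the 2 smallest unadjusted p values in each direction. Between NM401 and NM400 they would have been the 10 largest in each direction, and none passed. Up to 4 members per list with the smallest adjusted p were added for the mean response and each material, with 10 fixed genes: IL1B, TNF, CXCL8, CCL2, NLRP3, HMOX1, MT1X, CDKN1A, SQSTM1 and GPNMB. Genes differing between materials, those few called at IC5, at IC10 and in the mean response at IC10, genes shared by 3 materials, and those differing between control samples were named after their values were seen.

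Alternatives set in advance were no filter on dim genes, the brightest 40% of genes, the mean of all spots of a gene, no dye covariate, no array block, slide as a covariate (5 slides of 8 arrays), the replicate number as a block, each sample shifted to the same median, RIN as a covariate, the first technical run only, a change of at least 1.5-fold, each material fitted alone, the set tests named above, the omission of each material for the gene lists and the omission of each sample in turn. In the last, omitting 1 of 2 controls leaves a lone control that is assumed to vary like the other groups. Alternatives added after the data were seen were the technical axis as a covariate, the omission of each material for the count and named genes of the mean response, RIN limited to 10 as a covariate, and the omission of both NM400 IC20 replicate 1 and NM401 IC20 replicate 1. The technical axis is the first principal component of the residuals within groups. It held 32.2% of that variance, and slide explained 41.3% of the spread within groups along it. As a covariate it removes the largest component of the residual spread by construction. Smaller p values and larger counts with it are therefore partly built in. The mean response at IC10 and IC5 and the comparison of control samples between preparation days were also added.

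The procedure was tested on simulated data of 13464 genes with 50 genes changed at each fold. At IC20 of CHT it recovered 14% of genes changed 1.25-fold, 72% at 1.5-fold, 98% at 2-fold and 100% at 3-fold. In the mean response it recovered 96% at 1.25-fold and 100% above. For differences between materials it recovered 4%, 26%, 82% and 96%. False calls among unchanged genes numbered 11 for CHT, 7 in the mean response, 4 for BAY, 5 for material differences and 0 between NM401 and NM400. The array correlation was recovered as 0.308, a list of 25 genes shifted by 0.15 had adjusted p = 1.5e-05, and 0 of 28 unchanged lists were called. Simulated residuals were independent between genes, unlike those of the arrays.

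Left out of the gene comparisons were the spots without a gene symbol, which are used in the closing section alone, and the dimmest 40% of genes.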

Results

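RNA of THP-1 cells was measured on 2-colour Agilent gene expression arrays. THP-1 is a human monocytic leukaemia line. The cells had been turned into macrophages with PMA, a phorbol ester, and were then exposed for 24 h to 1 of 7 multi-walled carbon nanotube materials, which the labels call BAY, CHT, MIT, NM400, NM401, SES and SIG. NM400 and NM401 are reference materials. Each material was given at 3 concentrations named IC5, IC10 and IC20, after a nominal inhibition of 5, 10 and 20%. The IC20 concentration was 2.5 µg/ml for BAY, 15 µg/ml for CHT, 1.5 µg/ml for MIT, 10 µg/ml for SES and 2 µg/ml for NM400, NM401 and SIG. Every group of a material and concentration held 3 samples, and each material had 2 untreated control samples from its own plate. The 80 measured samples fell into 28 groups, and after averaging 3 technical repeats there were 77. The number of arrays, 40, limits the precision.

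Each sample pooled 2 wells, and the labels call the samples of a group biological replicates without saying whether they came from separate cultures. The p values therefore measure the spread between these samples. The SD of the difference between 2 measurements of the same RNA had a median of 0.251 on the log2 scale (3 pairs), and that between 2 replicates of a group a median of 0.239 (70 pairs). The comparisons of IC5, IC10, IC20, trends and materials, the gene lists and the alternatives to them were chosen before the data were examined, apart from those described as added. Values below are log2 fold changes of exposed samples against controls of the same plate, with SE and limma p values adjusted over the 13464 genes tested.

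The mean over the 7 materials at IC20 gives the average response at equal nominal inhibition. This mean compares 21 exposed with 14 control samples. Strong responses to some materials can carry it, so a gene called in it need not respond to each material. In it 378 genes rose and 227 fell, 605 in all, with a median absolute log2 fold change of 0.205, and 5 changed by more than 1.5-fold. CYP1B1, a cytochrome P450 enzyme induced by the aryl hydrocarbon receptor (AhR), fell by 1.06 (SE 0.091, adjusted p = 1.6e-12) and was lower in 6 of the 7 materials. TIPARP, another AhR target, fell by 0.65 (SE 0.057, adjusted p = 1.6e-12), again in 6 materials. NCF1, a subunit of the NADPH oxidase, fell by 0.65 (SE 0.085, adjusted p = 3e-07), and the transporter gene SLC16A6 fell by 0.61 (SE 0.069, adjusted p = 5.6e-09), each in 6 materials. DCSTAMP, needed for the fusion of macrophages, fell by 0.49 (SE 0.047, adjusted p = 3.3e-11) in all 7 materials. The growth factor gene NRG1 (-0.59), NPTX1 (-0.57), the folate enzyme gene MTHFD2L (-0.56), the thrombomodulin gene THBD (-0.53) and the protease gene ADAMTS1 (-0.49) completed the 10 largest falls. The largest rise was that of PROC, which encodes protein C, by 0.44 (SE 0.069, adjusted p = 1.2e-05) in 7 materials. P2RX7, an ATP-gated channel, rose by 0.38, CD70 by 0.38, BIRC5, which encodes survivin, by 0.38 (SE 0.05, adjusted p = 4.4e-07), and CENPM, a centromere protein, by 0.36, each in 7 materials. SDS (0.34), HES4 (0.34), ANXA8L1 (0.33), E2F2 (0.33) and the histone gene H3C2 (0.32) followed.

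**Figure D1:**
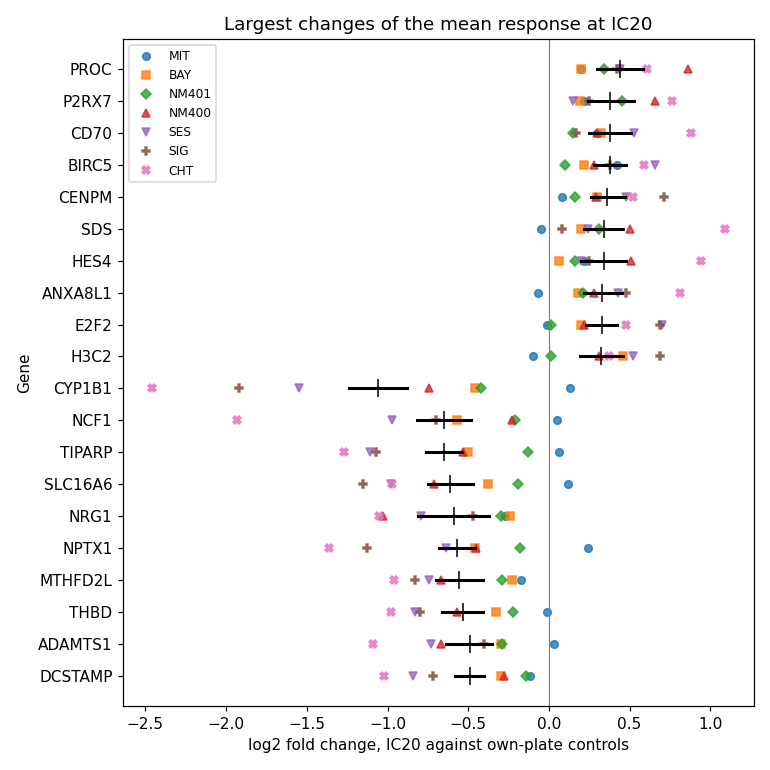
Log2 fold change at IC20 against controls of the 20 genes with the largest rises and falls in the mean response, with 1 point per material and the mean over 7 materials with its 95% confidence interval. CYP1B1 has the lowest mean, -1.06, and its material values run from -2.46 for CHT to 0.13 for MIT.

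The same count was compared under other choices and without single samples. Without BAY control replicate 2 the mean response held 998 genes, and without MIT control replicate 1 it held 426, the lowest of these counts. With slide as a covariate it held 905 genes, of which 594 were among the 605. With the technical axis as a covariate it held 1006, including all 605. With RIN as a covariate it held 454, of which 443 were among the 605. The axis, added after the data were seen, is the first principal component of the spread within groups. As a covariate it removes that part of the spread, so more calls with it are partly built in. Of 71 named genes past the test, 18 lost their call without 1 of the samples. The largest adjusted p of IFIT2 was 0.12, of NQO1 0.16, of MT1E 0.19, of MT1B 0.2, of PHLDA3 0.16, of INSIG1 0.11, of ABCA1 0.12, of NR1H3 0.15, of SPRY2 0.2 and of PDGFRA 0.18, all without BAY control replicate 1. That of GCLC was 0.1, of F13A1 0.065, of TIMP3 0.1 and of ANKRD37 0.069, all without SES control replicate 1. MT1M reached 0.12 and TRIB3 0.083 without MIT control replicate 1, MMP19 0.071 without NM400 control replicate 2, and VEGFA 0.066 without CHT control replicate 2. With the mean of all spots of a gene MT1E (adjusted p = 0.24) and MMP19 (0.11) did not pass. All 22 named called genes with 2 or more spots above the floor had their spots in 1 direction, but the sizes differed for some. NCF1 ran from -0.65 to -0.24 over 4 spots, THBS1 from -0.47 to -0.19 and CENPF from 0.12 to 0.29, while CYP1B1 ran from -1.06 to -1.05. Without the dye covariate IFIT2 (0.071), MT1B (0.058), PLK3 (0.073), PHLDA3 (0.081), ABCA1 (0.05) and MMP19 (0.084) did not.

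Named genes of the mean response were tested again without each material, where the number of samples is also smaller. CHT, SES and SIG, the materials with genes called alone at IC20, were not left out together. Without material CHT 20 of the 71 named genes past the test lost their call, among them SDS (0.21, adjusted p = 0.059), HES4 (0.24, 0.072), IL1B (-0.3, 0.063), HSPA1A (0.13, 0.17), GPNMB (0.09, 0.35), CD14 (-0.19, 0.062), CD83 (0.14, 0.055) and TRAF1 (0.19, 0.057). Without material SES 20 lost it, among them NQO1 (-0.23, 0.13), INSIG1 (-0.23, 0.11), F13A1 (0.17, 0.1) and ALDOC (0.15, 0.11). Without material SIG 22 did, among them FOXM1 (0.19, 0.075), MCM4 (0.13, 0.083), SLC7A11 (-0.2, 0.065), PHGDH (0.25, 0.063), DDIT4 (-0.17, 0.069), FDPS (0.13, 0.066) and EGR1 (-0.16, 0.054). Without NM400 9 lost it, without NM401 6 and without BAY 2, and without MIT 0 did. The other genes among the 10 largest rises and falls passed in each of these means.

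Materials were prepared on 3 days, here A (MIT, NM400 and NM401), B (BAY, SES and SIG) and C (CHT). The mean IC20 response of day A alone held 0 genes by limma, with 1204 at an unadjusted p under 0.05. Chance gives 673 on average, but as genes vary together a single count can lie far from it on either side. On day B 139 genes rose and 172 fell, and on day C, which is CHT alone, 137 rose and 102 fell. Between B and A, 20 genes differed, judged by the spread between samples of a group and not that between materials. In 7 comparisons on the same slide, each of 1 IC20 sample with 1 control sample and none of them for NM400, CYP1B1 was lower in 6, with -2.62 for CHT, -1.99 for SIG, -1.34 for SES, -0.68 for BAY, -0.22 for MIT and both -1.20 and 0.01 for NM401, the first of these from NM401 IC20 replicate 1, which stood apart from the other NM401 IC20 samples in CYP1B1. The AhR list was lower in 6 of these and the cell cycle list higher in 6. Leaving out each material in turn, the genes called in the other 6 went the same way in the omitted one for 65.6% (MIT), 77.3% (NM401), 79.7% (BAY), 84.8% (SIG), 87.6% (NM400), 90.5% (CHT) and 95.5% (SES).

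Gene lists fixed beforehand were compared with all other genes by camera. Of 29 lists 8 shifted in the mean response, and 7 of these calls held with an estimated correlation between genes. The AhR target list fell, with a median of -0.27 (adjusted p = 2.2e-15, and adjusted p = 4.1e-08 with an estimated correlation). Of its 7 members tested 4 fell, 0 rose and 3 did not pass; 4 also fell when adjusted over the list alone. Among them were CYP1B1, TIPARP and the AhR repressor AHRR, which fell by 0.35 (SE 0.048, adjusted p = 5e-07) in all 7 materials. The cell cycle list rose, with a median of 0.16 (adjusted p = 1.2e-12, and 5.2e-06 with an estimated correlation). In it 11 of 25 members rose, 0 fell and 14 did not pass, with 15 rising when adjusted over the list alone. CENPF rose by 0.29, the transcription factor gene FOXM1 by 0.27, the cyclin gene CCNB2 by 0.19 and the replication gene MCM4 by 0.17. Metallothioneins, which bind metals, rose with a median of 0.18 (adjusted p = 8e-05, and 0.025 with an estimated correlation). Of 12 members 4 rose, 0 fell and 8 did not pass, with 7 rising when adjusted over the list alone; MT2A rose by 0.32 and MT1M by 0.19.

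The matrix remodelling list fell with a median of -0.08 (adjusted p = 0.00059, and 0.025 with an estimated correlation). Of its 20 members 4 fell, 0 rose and 16 did not pass, with 4 falling when adjusted over the list alone. Thrombospondin THBS1 fell by 0.47 and the macrophage elastase MMP12 by 0.31. The cholesterol synthesis list rose with a median of 0.10 (adjusted p = 0.0093, and 0.025 with an estimated correlation). Of 15 members 4 rose, 1 fell and 10 did not pass, with 5 rising and 1 falling when adjusted over the list alone. The sterol reductase DHCR7 rose by 0.27 and INSIG1, which restrains the pathway, fell by 0.27. Without material CHT this list did not shift (median 0.02, adjusted p = 0.4). Chemokines fell with a median of -0.03 (adjusted p = 0.011, and 0.036 with an estimated correlation). Of 11 members 3 fell, 0 rose and 8 did not pass, with 1 rising and 3 falling when adjusted over the list alone. CXCL8 fell by 0.38 (SE 0.073, adjusted p = 0.00039), CXCL3 by 0.38 and CXCL2 by 0.28, all in 7 materials; without material CHT the list had adjusted p = 0.051. Markers of undifferentiated myeloid cells rose with a median of 0.11 (adjusted p = 0.024, and 0.025 with an estimated correlation), although 0 of 8 members rose, fell or passed when adjusted over the list alone; MYB had a log2 fold change of 0.11 and KIT of 0.10. Without material SES these markers did not shift (adjusted p = 0.098). The interferon list rose with a median of 0.09 (adjusted p = 0.016), but had adjusted p = 0.4 with an estimated correlation and adjusted p = 0.093 with slide as a covariate, 0.21 without material CHT and 0.098 without material SES. In it 1 of 18 members rose, 0 fell and 17 did not pass, with 1 rising when adjusted over the list alone; this was IFIT2 (0.17).

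The other 21 lists did not shift in the mean response. Of 10 proinflammatory cytokines 0 rose, 2 fell and 8 did not pass, with 3 falling when adjusted over the list alone (adjusted p = 0.097, and 0.049 with RIN as a covariate). TNF fell by 0.45 (SE 0.059, adjusted p = 3e-07) and IL1B by 0.39 (SE 0.086, adjusted p = 0.0025), each in 6 materials. Of 14 inflammasome genes 1 rose and 1 fell (adjusted p = 0.76). Of 15 NF-kB targets 2 rose, CD83 by 0.22 and TRAF1 by 0.21 (adjusted p of the list = 0.89). In the oxidative stress list of NRF2 targets 3 of 16 members fell, SLC7A11 by 0.27, NQO1 by 0.27 and GCLC by 0.20 (adjusted p of the list = 0.21). HSPA1A, which encodes the HSP70 chaperone, rose by 0.25 as 1 of 12 heat shock genes (adjusted p of the list = 0.43). In the endoplasmic reticulum stress list PSAT1 (0.31), PHGDH (0.31) and TRIB3 (0.20) rose and DDIT4 (-0.22) fell, 4 of 17 members (adjusted p of the list = 0.49). PLK3 (0.18) and PHLDA3 (0.19) rose and BTG2 (-0.27) fell among 15 p53 targets (adjusted p of the list = 0.94). In lipid handling the desaturase genes FADS2 (0.32) and FADS1 (0.23) and the receptor gene NR1H3 (0.13) rose, and the cholesterol exporter gene ABCA1 (-0.19) was 1 of 2 of 21 members that fell (adjusted p of the list = 0.43). In the lysosome list 1 of 19 rose and ATP6V0D2, a proton pump subunit, fell by 0.31 (adjusted p of the list = 0.57).

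Of 12 macrophage identity genes CD14 alone fell, by 0.26, and 0 rose (adjusted p of the list = 0.37). F13A1 rose by 0.21 as 1 of 8 genes of alternative activation (adjusted p of the list = 0.49). Of 17 hypoxia and glycolysis genes ALDOC (0.19) and ANKRD37 (0.17) rose and VEGFA (-0.25) fell (adjusted p of the list = 0.47), and adjusted over the list alone 5 rose and 1 fell. EGR1 fell by 0.21 and SPRY2 by 0.25 among 17 immediate early genes (adjusted p of the list = 0.099, and 0.047 with slide as a covariate). By limma 0 members passed in 5 lists: 17 phagocytosis receptors (adjusted p of the list = 0.66), 14 apoptosis genes (0.66), 20 cytoskeleton and adhesion genes (0.97), 15 cytosolic ribosome genes (0.37) and 19 oxidative phosphorylation genes (0.31). Among markers of other cell types, NKG7 rose by 0.27 as 1 of 6 lymphocyte genes (adjusted p of the list = 0.86), 0 of 3 epithelial genes passed (0.94) and PDGFRA fell by 0.17 as 1 of 3 fibroblast genes (0.36). Adjusted over the list alone, 1 gene rose and 1 fell in the inflammasome and lysosome lists, 3 rose among NF-kB targets, 3 fell among NRF2 targets, 1 rose among heat shock genes, 3 rose and 1 fell under endoplasmic reticulum stress, 4 rose and 3 fell among p53 targets, and 3 rose and 3 fell in lipid handling. Likewise 2 rose and 1 fell among phagocytosis receptors, 1 fell in macrophage identity, 1 rose in alternative activation, 2 fell among immediate early genes, 1 rose among lymphocyte markers and 1 rose and 2 fell among fibroblast markers. In the lists of NF-kB targets, p53 targets, cytoskeleton and lymphocyte markers the median was negative while camera gave the direction as up; the means of these lists were 0.01, 0, 0.01 and 0.02.

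**Figure D2:**
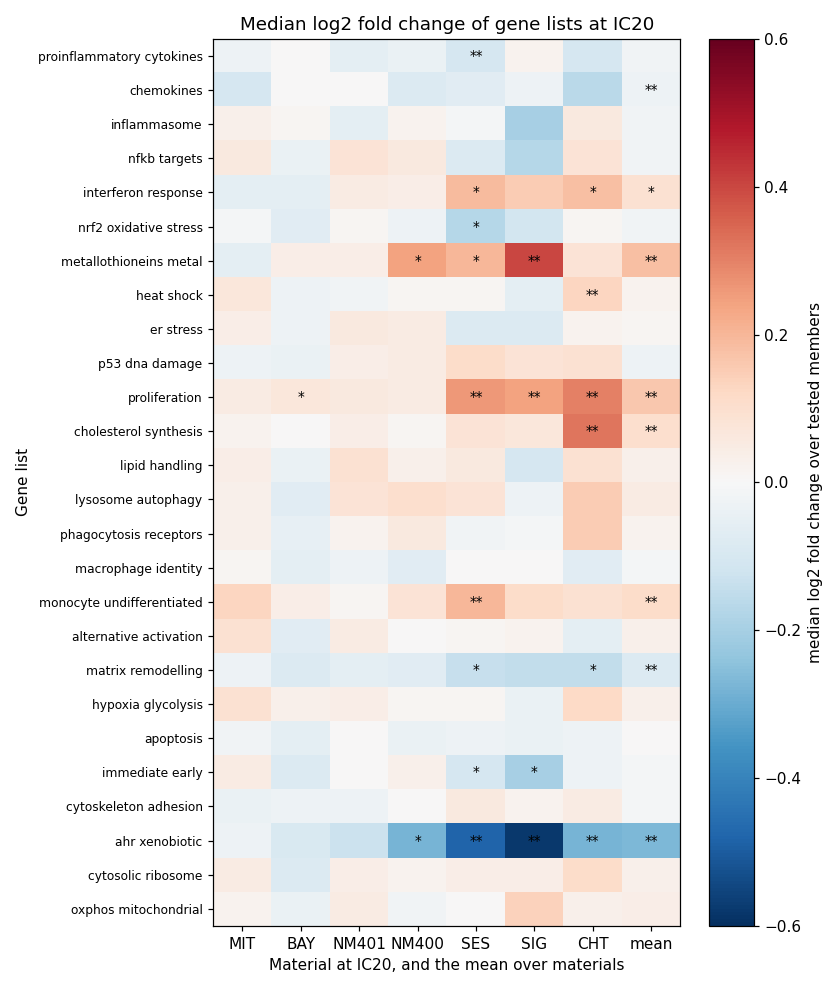
Median log2 fold change at IC20 of 26 gene lists in each of 7 materials and in their mean, on a colour scale from -0.6 to 0.6; an asterisk marks a camera call, a double asterisk a call that also holds with an estimated correlation. The AhR target list has a median of -0.58 for SIG and -0.27 in the mean, and the cell cycle list one of 0.30 for CHT and 0.16 in the mean.

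Of the fixed genes not yet given, CCL2 had a mean log2 fold change of 0.17 (adjusted p = 0.12), NLRP3 of -0.02 (0.88), HMOX1, a heme oxygenase, of -0.06 (0.48), MT1X of 0.00 (1), CDKN1A of -0.03 (0.84) and SQSTM1 of 0.10 (0.47), so that 0 of these 6 passed by limma, where 2287 of all genes had an unadjusted p under 0.05. GPNMB, a glycoprotein of macrophage lysosomes, rose by 0.21 (SE 0.05, adjusted p = 0.005).

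Each material was then compared with its own controls at IC20, 3 exposed with 2 control samples. With CHT 137 genes rose and 102 fell. CYP1B1 had a mean of 13.18 in the controls and 10.77 at IC20, and its fitted effect was -2.46 (SE 0.24, adjusted p = 8.9e-10). NCF1 fell by 1.93 (SE 0.23, adjusted p = 6.7e-08), NPTX1 by 1.36, TNF by 1.29 (SE 0.16, adjusted p = 1.3e-07), TIPARP by 1.27 (SE 0.15, adjusted p = 6.7e-08) and the chemokine receptor gene CXCR5 by 1.18. SDS, a serine dehydratase, rose by 1.09 (SE 0.16, adjusted p = 1.4e-05), HSPA1A by 0.97 (SE 0.13, adjusted p = 7.3e-07), GPNMB by 0.93 (SE 0.14, adjusted p = 7.2e-06) and SLAMF7 by 0.91. AK4 rose by 0.99 and HES4 by 0.94, but without CHT control replicate 1 the adjusted p of AK4 was 0.16, and without CHT control replicate 2 that of HES4 was 0.083. The count of 239 genes fell to 61 without CHT control replicate 1, to 86 without control replicate 2, to 122 without IC20 replicate 2 and to 124 without IC20 replicate 3. Of 34 named genes past the test 21 lost their call without 1 sample. With slide as a covariate 271 genes passed, 206 of them among the 239, and with the technical axis 333 did, 230 of them among the 239. With RIN 225 did, 214 of them among the 239.

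The lists of CHT that shifted were 6. AhR targets fell with a median of -0.28 (adjusted p = 1.5e-13, and 3.8e-07 with an estimated correlation), with 3 of 7 members falling, also when adjusted over the list alone, and AHRR by 0.73. The cell cycle list rose with a median of 0.30 (adjusted p = 1.4e-12, and 3.9e-06 with an estimated correlation), with 6 of 25 rising and 13 when adjusted over the list alone; TYMS rose by 0.67 and MCM3 by 0.50. Cholesterol synthesis rose with a median of 0.32 (adjusted p = 4.1e-08, and 8.4e-07 with an estimated correlation), with 2 of 15 members rising, CYP51A1 by 0.71 and ACAT2 by 0.50, and 5 when adjusted over the list alone. Heat shock genes rose with a median of 0.13 (adjusted p = 0.00022, and 0.0011 with an estimated correlation), where HSPA1A and HSPA1B (0.90) were the 2 of 12 members that rose, also when adjusted over the list alone. The interferon list rose with a median of 0.18 (adjusted p = 0.00049) but had adjusted p = 0.18 with an estimated correlation; 2 of 18 members rose, IFIT2 by 0.64 and CMPK2 by 0.72, and 4 when adjusted over the list alone. Matrix remodelling fell with a median of -0.15 (adjusted p = 0.0048) but had adjusted p = 0.087 with an estimated correlation; 1 of 20 members, MMP19, fell by 0.48, and 3 fell when adjusted over the list alone. Outside these lists, IL1B fell by 0.92 and CD14 by 0.74, and P2RX7 rose by 0.76 and CD83 by 0.71. Without CHT control replicate 1 the adjusted p was 0.69 for TYMS, 0.45 for MCM3, 0.3 for CYP51A1, 0.35 for ACAT2 and 0.54 for CMPK2. Without CHT control replicate 2 it was 0.078 for HSPA1B, 0.13 for IFIT2, 0.4 for MMP19, 0.46 for IL1B and 0.23 for P2RX7. Without the dye covariate TYMS (0.11), CD14 (0.075) and MMP19 (0.11) did not pass, and with slide as a covariate CMPK2 did not (0.1). With slide as a covariate, chemokines (adjusted p = 0.011, median -0.08) and metallothioneins (0.022, median 0.16) also passed. With the technical axis as a covariate chemokines (0.0099, median -0.1), metallothioneins (0.015, median 0.18), the lysosome list (0.037, median 0.13) and proinflammatory cytokines (0.049, median -0.05) did.

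With SES 21 genes rose and 21 fell at IC20. CYP1B1 had a mean of 12.48 in the controls and 10.98 at IC20, and its fitted effect was -1.55 (SE 0.24, adjusted p = 0.00013), TIPARP fell by 1.11 (SE 0.15, adjusted p = 1.1e-05), SLC16A6 by 0.98, NCF1 by 0.97, TNF by 0.95 (SE 0.16, adjusted p = 0.00039) and GPR183, an oxysterol receptor, by 0.94 (SE 0.14, adjusted p = 3.5e-05). The kinetochore gene KNL1 rose by 0.70, E2F2 by 0.70 (SE 0.13, adjusted p = 0.0018), BIRC5 by 0.66, B3GNT5 by 0.66, CDCA7 by 0.64 and the thymidine kinase gene TK1 by 0.62. TIPARP alone passed in every fit without 1 sample. Without SES control replicate 1 the adjusted p of CYP1B1 was 0.082, of TNF 0.082, of GPR183 0.073, of E2F2 0.66, of BIRC5 0.21, of SLC16A6 0.44, of NCF1 0.38, and of KNL1, B3GNT5, CDCA7 and TK1 1. Without the dye covariate KNL1 (0.21) and TK1 (0.29) did not pass either, and with the mean of all spots of a gene CDCA7 (0.14) and NCF1 (0.081) did not. The count of 42 genes became 3 without SES control replicate 1, 179 without control replicate 2, 26 without IC20 replicate 1, 10 without IC20 replicate 2 and 9 without IC20 replicate 3. With slide as a covariate 72 genes passed, 36 of them among the 42, with the technical axis 101, and with RIN 35, all among the 42.

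For SES 9 lists shifted, of which 4 held with an estimated correlation. The cell cycle list rose with a median of 0.26 (adjusted p = 8.4e-09, and 0.00025 with an estimated correlation), where by limma 0 of 25 members passed over all genes and 6 did when adjusted over the list alone. AhR targets fell with a median of -0.48 (adjusted p = 2.9e-08, and 0.00025 with an estimated correlation), CYP1B1 and TIPARP being the 2 of 7 members past the test, with 4 falling when adjusted over the list alone. Proinflammatory cytokines fell with a median of -0.10 (adjusted p = 0.019, and 0.03 with an estimated correlation), but had 0.054 with slide as a covariate; TNF was the 1 of 10 members that fell, and 2 fell when adjusted over the list alone. Undifferentiated myeloid markers rose with a median of 0.20 (adjusted p = 0.011, and 0.015 with an estimated correlation), with 0 of 8 members past limma's test and 1 when adjusted over the list alone. The others were lost. The interferon list (median 0.19, adjusted p = 0.0013) had adjusted p = 0.22 with an estimated correlation, NRF2 targets (-0.17, 0.011) had 0.064, metallothioneins (0.20, 0.011) 0.21, matrix remodelling (-0.14, 0.015) 0.14 and immediate early genes (-0.10, 0.019) 0.22. By limma 0 of their members passed over all genes, and adjusted over the list alone 1 metallothionein rose, 2 matrix genes and 1 immediate early gene fell, and 0 passed in the other 2 lists.

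With SIG 51 genes rose and 59 fell at IC20. CYP1B1 had a mean of 12.43 in the controls and 10.52 at IC20, and its fitted effect was -1.92 (SE 0.24, adjusted p = 2.4e-06), SLC16A6 fell by 1.15 (SE 0.19, adjusted p = 0.00019), NPTX1 by 1.13 (SE 0.15, adjusted p = 4.3e-06), TIPARP by 1.07 (SE 0.15, adjusted p = 1.3e-05), TBC1D8 by 0.94 and MTHFD2L by 0.83. The cell cycle kinase gene PKMYT1 rose by 0.90 (SE 0.15, adjusted p = 0.00028), MT1L by 0.90, TMEM97 by 0.81, MCM5 by 0.80, FOXM1 by 0.78 (SE 0.15, adjusted p = 0.0017) and GTSE1 by 0.77. Of 31 named genes past the test 26 lost their call without 1 sample, among them TMEM97 with adjusted p = 0.069 without SIG control replicate 1 and, without SIG control replicate 2, MT1L with 0.5, MCM5 with 0.5, FOXM1 with 0.093, GTSE1 with 0.34, TBC1D8 with 0.8 and MTHFD2L with 0.28; PKMYT1, CYP1B1, SLC16A6, NPTX1 and TIPARP kept theirs. The count of 110 genes became 16 without SIG control replicate 1, 15 without control replicate 2, 41 without IC20 replicate 1 and 42 without IC20 replicate 2. The SIG controls stood apart on the technical axis, at a mean of 1.35 against -0.44 for the IC20 samples. With this axis as a covariate 80 genes passed, 53 of them among the 110, and with RIN, the RNA integrity number, 44 did, or 57 with the 1 label above the scale's maximum, 10.8 for CHT IC20 replicate 2, limited to 10.

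For SIG 4 lists shifted. The cell cycle list rose with a median of 0.24 (adjusted p = 4.4e-08, and 0.0011 with an estimated correlation), with 4 of 25 members rising and 9 when adjusted over the list alone. AhR targets fell with a median of -0.58 (adjusted p = 3.2e-06, and 0.0025 with an estimated correlation), with 3 of 7 falling and 4 when adjusted over the list alone; AHRR fell by 0.58. Metallothioneins rose with a median of 0.40 (adjusted p = 1.5e-05, and 0.025 with an estimated correlation), with 2 of 12 rising, MT1L and MT1B (0.62), and 6 when adjusted over the list alone. With the technical axis as a covariate the medians were 0.31 for the cell cycle list, -0.39 for AhR targets and 0.24 for metallothioneins (adjusted p = 1.9e-23, 3.8e-11 and 1.5e-07). Immediate early genes fell with a median of -0.20 (adjusted p = 0.026) but had adjusted p = 0.33 with an estimated correlation, 0.078 with slide and 0.12 with the technical axis as a covariate; EGR1, 1 of 17, fell by 0.50, and 1 member fell when adjusted over the list alone. In other lists CXCL8 fell by 0.82, THBS1 by 0.75, INSIG1 by 0.81, ATP6V0D2 by 0.72 and SLC7A11 by 0.71, and the sterol genes DHCR7 (0.60) and FDPS (0.44) rose. Without SIG control replicate 2 the adjusted p was 0.5 for AHRR, 0.68 for MT1B, 0.59 for EGR1, 0.28 for CXCL8, 0.8 for THBS1, 0.58 for INSIG1, 0.2 for SLC7A11, 0.7 for DHCR7 and 0.53 for FDPS, and without SIG control replicate 1 it was 0.13 for ATP6V0D2. Without the dye covariate MT1B (0.054), FDPS (0.066) and THBS1 (0.055) did not pass.

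**Figure D3:**
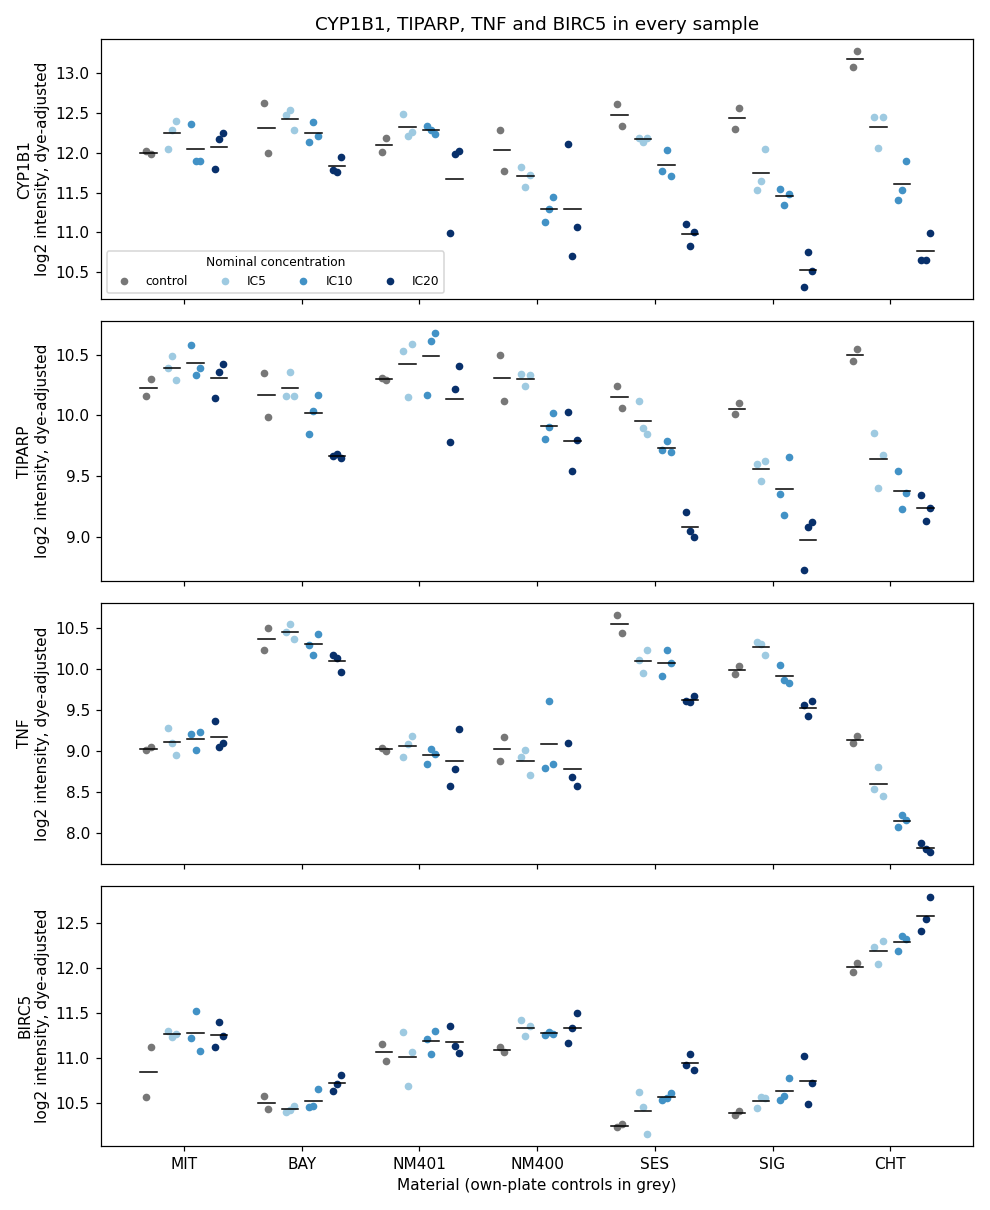
Log2 values, adjusted for dye, of CYP1B1, TIPARP, TNF and BIRC5 in each sample of the 28 groups, with black bars at the group means. The log2 fold change of CYP1B1 at IC20 is -2.46 for CHT, -1.92 for SIG and -1.55 for SES.

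The genes called in these 3 materials overlapped. CHT and SES shared 18 falling genes, where chance gives 0.16, CHT and SIG shared 23 (0.45) and SES and SIG 14 (0.092). Rising genes shared numbered 7 (0.21), 6 (0.52) and 4 (0.08) in the same order. All 3 materials shared 13 falling genes, among them CYP1B1, TIPARP, DCSTAMP, NPTX1, CXCR5, GPR183, THBD and the axon guidance gene NTN1, and 2 rising genes, E2F2 and CDCA5, a regulator of sister chromatid cohesion.

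In the other 4 materials 0 genes passed limma's test at IC20. The unadjusted p was under 0.05 for 259 genes with BAY, 511 with MIT, 639 with NM400 and 280 with NM401. Chance gives 673 on average. PROC had a log2 fold change of 0.86 with NM400 (SE 0.19, adjusted p = 0.29) and FCGR2C one of 0.46, while SLC16A6 had -0.71 and ACBD7 -0.56. The smallest p values with BAY were those of KRTAP5-11 (0.59), ARHGAP32 (0.31), RIPOR3 (-0.39) and TM4SF18 (-0.49), and with MIT those of LOC101929021 (0.45), TCAP (0.40), POM121L12 (-0.60) and RPAP1 (-0.37). With NM401 they were those of FKBPL (0.42), AK9 (0.41), PLA2G4F (-0.46) and KIR3DL1 (-0.41). Some of these genes were dim. With BAY, RIPOR3 had means of 6.177 in the controls and 5.775 at IC20, and TM4SF18 of 6.091 and 5.617, where the median of all spots was 5.711. CYP1B1 had a log2 fold change of -0.74 with NM400, -0.46 with BAY, -0.42 with NM401 and 0.13 with MIT, and TNF had -0.27, -0.26, -0.07 and 0.10 in that order. With NM400 IC20 replicate 1 and NM401 IC20 replicate 1 left out CYP1B1 had -1.18 with NM400 (SE 0.19, adjusted p = 0.00075) and -0.12 with NM401 (SE 0.18, adjusted p = 1). The left-out samples were picked for their CYP1B1 values, so these effects and p values follow in part from that choice. Metallothioneins rose with NM400 (median 0.24, adjusted p = 0.00072) and AhR targets fell (median -0.28, adjusted p = 0.00072), but these had adjusted p = 0.16 and adjusted p = 0.093 with an estimated correlation; by limma 0 of their members passed, and 3 AhR targets fell when adjusted over the list alone. The cell cycle list rose with BAY (median 0.07, adjusted p = 0.029) but had adjusted p = 0.27 with an estimated correlation. With MIT and NM401 0 lists shifted. Without MIT control replicate 2 MIT had 13 genes, without NM400 IC20 replicate 1 NM400 had 14, and without NM401 control replicate 2 NM401 had 1.

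The lower concentrations ask at which nominal inhibition the changes begin. At IC10 of CHT 10 genes fell and 0 rose, among them CYP1B1 by 1.54, NCF1 by 1.12, TIPARP by 1.10, NPTX1 by 1.01, TNF by 0.99 and CXCR5 by 0.91. Without CHT control replicate 1 there were 5 and without control replicate 2 there were 2. At IC5 of CHT TIPARP alone fell, by 0.80 (SE 0.15, adjusted p = 0.034), and 0 genes passed without IC5 replicate 2, IC5 replicate 3, control replicate 1 or control replicate 2. At IC10 of NM400 the calprotectin gene S100A9 fell by 0.65 (adjusted p = 0.039), ALOX5AP fell by 0.61 (0.048) and CD83 rose by 0.53 (0.045), and 0 genes passed without IC10 replicate 2, control replicate 1 or control replicate 2. By limma 0 genes passed at IC10 of the others. There the unadjusted p was under 0.05 for 286 genes with BAY, 392 with MIT, 339 with NM401, 959 with SES and 782 with SIG. Chance gives 673 on average. At IC5 of the others 0 passed by limma too, with 356 for BAY, 682 for MIT, 490 for NM400, 494 for NM401, 1651 for SES and 3179 for SIG. With the technical axis as a covariate the last of these was 431. Leaving out 1 sample gave calls in some of these comparisons. At IC10 SES had 37 genes and at IC5 184 without SES control replicate 2, and MIT had 3 at IC10 and 4 at IC5 without MIT control replicate 2. MIT had 1 at IC5 without IC5 replicate 2, NM400 had 4 at IC5 without IC5 replicate 1 and 1 without IC5 replicate 2, and NM401 had 1 at IC10 without IC10 replicate 3. The mean over the 7 materials, added for these concentrations after the data were seen, held 8 falling genes at IC10, with CYP1B1 at -0.52, NPTX1 at -0.33, TIPARP at -0.31, S100A8 at -0.30 and DCSTAMP at -0.27. At IC5 it held 0 by limma, with 298 genes at an unadjusted p under 0.05. At IC10 5 of 29 lists shifted by camera, and 2 of these calls held with an estimated correlation: AhR targets fell (median -0.10) and the cell cycle list rose (median 0.06), each with adjusted p = 9e-07, and 0.0023 with an estimated correlation. At IC5 1 list shifted, interferon response (median 0.07, adjusted p = 1e-04), but had adjusted p = 0.3 with an estimated correlation.

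A trend across control, IC5, IC10 and IC20 was fitted per 10 percentage points of nominal inhibition. For CHT 223 genes rose and 147 fell, 370 in all, of which 332 were ordered from IC5 through IC10 to IC20. Genes were picked by a trend over the same group means, so such an order is partly built in, here and for SES and SIG. CYP1B1 changed by -1.21 per 10 points (SE 0.11, adjusted p = 1e-10), with log2 fold changes of -0.84, -1.54 and -2.46. TNF had -0.5, -0.99 and -1.29, and SDS 0.35, 0.62 and 1.09. For SES 34 genes rose and 45 fell, with 71 of 79 ordered; CYP1B1 changed by -0.79 per 10 points (adjusted p = 1e-05), TIPARP had -0.13, -0.40 and -1.11 and E2F2 0.27, 0.38 and 0.70. For SIG 49 rose and 56 fell, with 77 of 105 ordered; CYP1B1 changed by -0.93 per 10 points (adjusted p = 8.1e-07), with log2 fold changes of -0.69, -1.01 and -1.92. The trend and IC20 comparisons share samples and shared 238 genes for CHT, 39 for SES and 89 for SIG. By limma 0 genes had a trend in the others. The unadjusted p was under 0.05 for 309 with BAY, 545 with MIT, 669 with NM400 and 253 with NM401. Chance gives 673 on average.

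Trend counts also moved with single samples. For CHT there were 243 without IC20 replicate 1, 171 without IC20 replicate 2, 196 without IC20 replicate 3, 127 without control replicate 1 and 187 without control replicate 2. For SES there were 23 without IC20 replicate 2, 25 without IC20 replicate 3, 19 without control replicate 1 and 144 without control replicate 2. For SIG there were 47 without IC20 replicate 1, 47 without IC20 replicate 2, 41 without control replicate 1 and 20 without control replicate 2. MIT had 2 without IC20 replicate 2 and 2 without control replicate 2, NM400 had 24 without IC20 replicate 1, and NM401 had 2 without control replicate 2.

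Whether the materials differ at IC20 was tested with a moderated F test of equal effects. It called 19 genes, with 593 at an unadjusted p under 0.05. CYP1B1 ranged from -2.46 with CHT to 0.13 with MIT (adjusted p = 1.2e-05), NPTX1 from -1.36 to 0.24 (adjusted p = 2.7e-05), TIPARP from -1.27 to 0.06 (adjusted p = 5.8e-05) and TNF from -1.29 to 0.10 (adjusted p = 0.00049). HSPA1A ranged from -0.14 with SIG to 0.97 with CHT (adjusted p = 0.0034) and GPNMB from -0.14 with SIG to 0.93 with CHT (adjusted p = 0.016). CXCR5, DCSTAMP, NCF1, the neurotrophin gene BDNF, ARID3B, CDCP1, GPR183, SMIM3, MGAT3, the adenosine receptor gene ADORA2B, SLC16A6, CD244 and the cytokine gene IL24 made up the rest. The count was 7 without CHT control replicate 1, 12 without CHT control replicate 2, 11 without MIT control replicate 1, 12 without NM401 control replicate 1 and 31 without NM401 IC20 replicate 1. With the technical axis as a covariate it was 43, and without the dye covariate 10.

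Materials given at the same mass concentration were compared there. At 0.5 µg/ml 0 genes differed between materials by limma's F test (899 at an unadjusted p under 0.05), and at 1 µg/ml 0 did (272). At 2 µg/ml, given to NM400, NM401, SES and SIG, 1 gene did, with 1659 at an unadjusted p under 0.05. This mass was IC5 for SES and IC20 for the others, so nominal inhibition was not equal there. The gene that differed is given next. This was the pseudogene GXYLT1P3 (adjusted p = 0.018), with 0.15 for NM400, -0.02 for NM401, 0.54 for SES and -0.45 for SIG. The count was 18 without NM400 IC20 replicate 1, 6 without NM400 IC20 replicate 2, 16 without NM400 control replicate 2, 10 without NM401 IC20 replicate 1, 2 without NM401 IC20 replicate 2 and 8 without NM401 control replicate 2. It was 0 without SES IC5 replicate 1, 2 without SES IC5 replicate 2, 2 without SES IC5 replicate 3, 0 without SES control replicate 1 and 13 without SES control replicate 2. It was 0 without SIG IC20 replicate 1, 0 without SIG IC20 replicate 2, 5 without SIG IC20 replicate 3 and 0 without SIG control replicate 2. CYP1B1 did not pass here over all genes (adjusted p = 0.056), and it and TIPARP were compared between pairs of materials after their values were seen. For CYP1B1 alone, SES minus SIG was 1.70 (95% CI 1.01 to 2.39, p adjusted over 6 pairs by limma 5e-05), NM401 minus SIG 1.50 (0.83 to 2.17, 0.00012) and NM400 minus SIG 1.18 (0.49 to 1.88, 0.0025). NM400 minus NM401 was -0.32 (-0.99 to 0.35, 0.42), NM400 minus SES -0.52 (-1.18 to 0.14, 0.18) and NM401 minus SES -0.20 (-0.86 to 0.45, 0.53). With IC20 replicate 1 of NM400 and of NM401 left out, NM401 minus NM400 was 1.07 in place of 0.32 (SE 0.26, adjusted p over all genes = 0.45). Each left-out sample lay towards the other material in CYP1B1, so that a larger difference followed from the choice. TIPARP gave 0.94 for SES minus SIG (0.51 to 1.37, 0.00016), 0.93 for NM401 minus SIG (0.52 to 1.35, 0.00016) and 0.54 for NM400 minus SIG (0.11 to 0.97, 0.03). It gave -0.39 for NM400 minus NM401 (-0.81 to 0.02, 0.076), -0.40 for NM400 minus SES (-0.81 to 0.01, 0.076) and 0 for NM401 minus SES (-0.41 to 0.40, 0.98). Adjusted over all genes, SES minus SIG passed for CYP1B1 (adjusted p = 0.016) and TIPARP (adjusted p = 0.033), while NM401 minus SIG (adjusted p = 0.078 for each) and NM400 minus SIG (adjusted p = 0.97 for each) did not. With the technical axis as a covariate 0 genes differed between these materials at 2 µg/ml by limma's F test, and the pairs were not tested with it.

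NM401 and NM400 share 3 concentrations, which allows the reference materials to be compared directly. At 2 µg/ml 0 genes differed by limma, with 199 at an unadjusted p under 0.05, at 1 µg/ml 0 (350) and at 0.5 µg/ml 0 (405). The median 95% interval had a half-width of 0.388 at 2 µg/ml, and for 13113 genes, 97.4%, it lay inside a 2-fold change. With NM400 IC20 replicate 1 and NM401 IC20 replicate 1 both left out, a choice added after their CYP1B1 values were seen, 1 gene differed, PROC, lower with NM401 by 1.09 (SE 0.21, adjusted p = 0.031). In that fit NM400 had 27 genes at IC20, among them PROC at 1.17 (adjusted p = 4.1e-06) and CYP1B1 at -1.18 (SE 0.19, adjusted p = 0.00075), and the mean response held 593. As PROC crossed between the 2 samples like CYP1B1, the calls of both genes follow in part from that choice. Each of these 2 samples lay with the other material's IC20 samples for CYP1B1, PROC, SDS, P2RX7 and HES4, and for 191 of 516 genes called in the mean over the other 5 materials; for the other 8 pairs of an NM400 with an NM401 IC20 sample the highest such number was 59.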

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

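The tests of CYP1B1 against mass concentration, preparation day and the technical axis were chosen after the result was seen; so were the count of crossed genes and the limit on RIN, while the other tests of SIG IC5 and of exchanged samples were written down first.

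The effect at IC20 differed between the 7 materials for 19 genes by a moderated F test of the difference. The adjusted p was 1.2e-05 for CYP1B1, 2.7e-05 for NPTX1, 5.8e-05 for TIPARP, 0.00049 for TNF, 0.001 for CXCR5, 0.0024 for DCSTAMP, 0.0028 for NCF1, 0.0034 for BDNF, 0.0034 for HSPA1A, 0.0043 for ARID3B and 0.0076 for CDCP1. It was 0.016 for GPNMB, 0.019 for GPR183, 0.019 for SMIM3, 0.02 for MGAT3, 0.024 for ADORA2B, 0.024 for SLC16A6, 0.026 for CD244 and 0.049 for IL24. The lowest effect was with CHT for NPTX1 (-1.36), NCF1 (-1.93), CXCR5 (-1.18), CDCP1 (-1.13), DCSTAMP (-1.02) and BDNF (-0.91), with SIG for SLC16A6 (-1.15) and IL24 (-0.75), and with SES for GPR183 (-0.94). At 2 µg/ml GXYLT1P3 differed between NM400, NM401, SES and SIG (adjusted p = 0.018, from -0.45 with SIG to 0.54 with SES), but 0 genes did by limma with the technical axis as a covariate, or without SES IC5 replicate 1, SES control replicate 1, SIG IC20 replicate 1, SIG IC20 replicate 2 or SIG control replicate 2. The mean IC20 effect differed between preparation days A and B for 20 genes, judged by the spread between samples of a group and not that between materials. Outside the named genes, 25 of 5542 spots without a gene symbol passed in the mean response at IC20, 12 higher and 13 lower.

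CYP1B1 fell by different amounts between materials at IC20, from -2.46 to 0.13. The technical axis is argued against as the whole cause, since with it as a covariate the effects still differed (F test, adjusted p = 7.3e-08). The axis was taken from the residuals of the same samples, so the size of that p is partly built in. Preparation day as the whole cause is argued against only among picked genes. CYP1B1 was among 55 genes picked by the mean effects of the days. BAY, SES and SIG, prepared on 1 day, differed in it by up to 1.46 (limma F test, adjusted p over the 55 genes = 0.024, and 0.89 over all genes). At 2 µg/ml SES minus SIG passed over all genes by limma for CYP1B1 (1.70, adjusted p = 0.016) and TIPARP (0.94, adjusted p = 0.033). This goes against mass concentration alone, but SES was at IC5 and SIG at IC20, so nominal inhibition differed too. For CYP1B1 the pairs at IC20 with SIG did not pass (limma, adjusted p = 0.078 for NM401 and 0.97 for NM400). Also, SES minus SIG was singled out among 6 pairs. Over the 6 pairs and all genes together CYP1B1 had adjusted p = 0.074 by limma (F test of the 4 materials, adjusted p = 0.056). On the technical axis SES IC5 had a mean of 0.91 and its controls -0.39, while SIG IC20 had -0.44 and its controls 1.35. The pair was not tested with the axis as a covariate, where 0 genes differed between the 4 materials by limma's F test. An earlier form of both tests, with the gene picked in one part of the samples by its spread of effects and tested in the other, picked FARSB and RNA18SN5 (CYP1B1 at rank 81 and 4) and so decided nothing, although CYP1B1 differed there (larger adjusted p over 4 tests 2.4e-05 for mass concentration and 0.012 for preparation day). Mass concentration, nominal inhibition and the material itself thus cannot be told apart by these tests, and each material also had its own plate. Preparation day was judged over 55 picked genes and mass concentration over all genes, so their adjusted p values do not rank these explanations.

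At SIG IC5 3179 genes had an unadjusted p under 0.05, where chance gives 673 on average, and 0 passed limma's adjusted test. The SIG controls lay at 0.84 and 1.87 on the technical axis and the SIG IC5 samples at a mean of -0.99. With this axis as a covariate the number was 431, in line with a displacement of the SIG controls along it. With RIN as a covariate it was 2420, and 2682 with the 1 labelled RIN above the scale's maximum, 10.8 for CHT IC20 replicate 2, limited to 10, which argues against RNA integrity as the whole cause. No biological explanation was tested, and a response that runs along the axis stays open.

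In CYP1B1, NM400 IC20 replicate 1 (12.11) and NM401 IC20 replicate 1 (10.99) each stood apart from its group towards the other group, whose other samples had 10.71 and 11.07 with NM400 and 11.99 and 12.02 with NM401. PROC (8.58 and 9.32, against 9.43 and 9.32 with NM400 and 8.42 and 8.33 with NM401), SDS, P2RX7 and HES4 crossed in the same way. Of 516 genes called in the mean over the other 5 materials 191 did, against at most 59 for the other pairs among the 9 of these IC20 samples, a number of pairs too small to exclude chance. A score of 200 genes that differ between the plates placed 13 of 16 held-out samples on their own side, fewer than the number set in advance, with NM400 IC20 replicate 1 on its own side (-0.52) and NM401 IC20 replicate 1 close to the midpoint on the other (-0.06). The responding genes thus go with an exchange and the plate score does not settle it, so that an exchange and a different strength of response in these 2 samples cannot be told apart; no biological explanation was tested.

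Chance is argued against for the mean response at IC20. Of 100 splits of the IC20 and control labels within materials 1, the real split, gave as many as 605 genes. The highest of the others gave 9. In the other splits the exposure effects add to the spread within groups, which lowers their counts. The share cannot fall below 1 of 100.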

How the results depend on the processing

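The technical axis, RIN limited to 10 and the omission of both doubted samples (NM400 IC20 replicate 1 and NM401 IC20 replicate 1) were chosen after the data were seen. So was the omission of each material for the count and named genes of the mean response. With 2 controls per material, leaving out 1 leaves a lone control that is assumed to vary like the other groups. Signal over background limits the dimmest genes, which were left out. No named gene called in the report reversed with the mean of all spots, slide, the replicate block or a common median. Nor did one without dye, the array block, 1 sample or 1 material. Named genes were not followed as a set under the other settings, among them RIN and the technical axis. No called list reversed in the set tests or without a material. In the mean response, CHT, SES and SIG none reversed with RIN, slide or the technical axis. The BAY, NM401 against NM400, 0.5 µg/ml and 1 µg/ml counts stayed at 0 by limma without each sample. Counts not given below were within 1.5 times the reported ones. Where a setting changes a count the cause was not tested, except that fewer samples or genes follow from omissions and filters.

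Without the filter on dim genes, IC20 held 1 gene for NM400 and 21 for SES, IC10 of NM400 0, IC5 1 for BAY and 1 for SES, and the trend 2 for NM400 and 38 for SES. With the brightest 40% of genes, 7 genes differed between materials at 2 µg/ml. With the mean of all spots of a gene, NM400 had 1 at IC20 and 1 in the trend, SIG 1 at IC10, CHT 0 at IC5, and 9 differed at 2 µg/ml. Without the dye covariate, SES had 17 at IC20 and 36 in the trend, NM400 1 at IC10, and 10 differed between materials at IC20. Without the array block, SES had 22 at IC20 and 45 in the trend, and NM400 1 in the trend. With slide as a covariate, SES had 72 at IC20, CHT 24 at IC10 and 2 at IC5, and 3 differed at 2 µg/ml; the array correlation was then 0.042. With each sample shifted to the same median, 5 differed at 2 µg/ml. With RIN as a covariate, SIG had 44 at IC20 and NM400 1 at IC10, and with RIN limited to 10 SIG had 57 at IC20 and 2 differed at 2 µg/ml. With the first technical run only, NM400 had 1 at IC10 and 8 genes differed at 2 µg/ml.

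With the replicate number as a block, IC20 held 27 genes for SES and 632 for SIG, IC10 of NM400 0, IC5 1 for SES and 1061 for SIG, the trend 48 for SES and 187 for SIG, and 6 differed at 2 µg/ml. The numbers do not pair the samples: residuals of samples with the same number had mean correlations from -0.05 (MIT) to 0.16 (SIG), and the lowest single one was -0.56 (SES). The counts with this block therefore do not replace the reported ones.

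With the technical axis as a covariate, SES had 101 genes at IC20 and 155 in the trend, CHT 38 at IC10 and NM400 5 at IC10, the mean response 1006, and 43 differed between materials at IC20 and 0 at 2 µg/ml. With both doubted samples left out, NM400 had 27 at IC20 and 33 in the trend, 1 differed between NM401 and NM400, 40 between materials at IC20 and 24 at 2 µg/ml. With a change of at least 1.5-fold required, IC20 held 107 genes for CHT, 23 for SES and 62 for SIG, the trend 5, 1 and 1 in that order, and the mean response 5. With each material fitted alone, IC20 held 69 for CHT, 11 for SES and 11 for SIG, IC10 6 for CHT and 0 for NM400, IC5 0 for CHT, and the trend 123 for CHT, 22 for SES and 22 for SIG. Over 6 materials the mean response held 336 without CHT, 314 without SES and 341 without SIG.

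Leaving out 1 sample at a time, the mean response ranged from 426 to 998 genes, material differences at IC20 from 7 to 31 and those at 2 µg/ml from 0 to 18. At IC20 the count ranged from 61 to 167 for CHT, 3 to 179 for SES, 15 to 95 for SIG, 0 to 13 for MIT, 0 to 14 for NM400 and 0 to 1 for NM401. Trends ranged from 127 to 418 for CHT, 19 to 144 for SES, 20 to 124 for SIG, 0 to 2 for MIT, 0 to 24 for NM400 and 0 to 2 for NM401. At IC10 they ranged from 2 to 9 for CHT, 0 to 3 for MIT, 0 to 2 for NM400, 0 to 1 for NM401 and 0 to 37 for SES. At IC5 they ranged from 0 to 1 for CHT, 0 to 4 for MIT, 0 to 4 for NM400 and 0 to 184 for SES. The extremes for CHT at IC20 came without CHT control replicate 1 and CHT IC20 replicate 1, for SES without SES control replicates 1 and 2, and for SIG without SIG control replicate 2 and SIG IC20 replicate 3.

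Over the named genes in each result, leaving out 1 sample gave 8630 values on the same side of the test, 324 that no longer passed and 66 that newly passed. With slide as a covariate these were 965, 8 and 27, with the replicate block 968, 10 and 22, with the mean of all spots 957, 9 and 8, without dye 981, 18 and 1, without the array block 989, 8 and 3, and with a common median 998, 0 and 2. Of the gene lists, 12 of 232 calls or non-calls weakened with an estimated correlation and 220 did not, and with fry 9 weakened, 5 strengthened and 218 did not change. Genes and lists that had not passed could not weaken, so these totals understate the share of calls lost. With an estimated correlation 7 of 8 list calls held in the mean response, 4 of 6 for CHT, 4 of 9 for SES and 3 of 4 for SIG. For BAY 0 of 1 held and for NM400 0 of 2.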

Other observations

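The tests of the cell cycle genes, the checks of the graded response with the technical axis, the comparison of control samples and its splits were chosen after the data were seen.

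Untreated controls of preparation day B (6 of BAY, SES and SIG) and day A (6 of MIT, NM400 and NM401) differed in 3144 genes. Of these 1570 were higher and 1574 lower on day B, and 479 differed by more than 1.5-fold. The gene and list p values of this comparison rest on the spread between samples of a plate, not that between plates of a day. They therefore do not test day against plate. RIN was 8.8 to 10 in the controls of day B and 9.8 to 10 in those of day A, and the differences correlated at 0.32 with the technical axis over genes; with RIN as a covariate 2336 genes differed, and with the axis 3509. The scavenger receptor gene CD163 was higher on day B by 1.81 (SE 0.063, adjusted p = 7.3e-32), from 9.575 to 11.38. The protease inhibitor gene TFPI2 was higher by 2.25 (SE 0.11), FAP by 2.09, the chemokine gene CCL20 by 1.96, MET by 1.92 and the collagenase gene MMP8 by 1.80. IL1B was higher by 1.46, TNF by 1.27, CXCL8 by 0.81, CCL2 by 0.74, CDKN1A by 0.51, HMOX1 by 0.50, NLRP3 by 0.43 and GPNMB by 0.41, MT1X was lower by 0.36, and SQSTM1 did not pass (0.18, adjusted p = 0.25). The desaturase gene FADS2 was lower, at -2.27 (SE 0.085), as were PNOC (-2.26), the fractalkine receptor gene CX3CR1 (-1.47), DHCR7 (-1.37), FADS1 (-1.35) and SCD (-1.30).

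By camera 14 of 29 lists differed, and 13 of these calls held with an estimated correlation; the metallothionein call did not (adjusted p = 0.0036, and 0.099 with an estimated correlation). Chemokines were higher on day B (8 of 11 members higher and 1 lower, median 0.74, adjusted p = 3.1e-12), as were matrix remodelling (12 of 20 higher, median 0.51, adjusted p = 1.3e-13), phagocytosis receptors (10 of 17, median 0.42, adjusted p = 3.2e-09), proinflammatory cytokines (6 of 10, median 0.49, adjusted p = 1.2e-07) and alternative activation (7 of 8, median 0.56, adjusted p = 2.4e-05). Cholesterol synthesis was lower (14 of 15, median -0.63, adjusted p = 2.9e-17), as were the cell cycle list (19 of 25, median -0.38, adjusted p = 1.5e-11) and lipid handling (12 of 21 lower and 6 higher, median -0.33, adjusted p = 2.6e-09). NF-kB targets (8 of 15 higher, median 0.32, adjusted p = 1.2e-06), immediate early genes (10 of 17, median 0.27, adjusted p = 4.1e-05) and hypoxia and glycolysis (8 of 17, median 0.20, adjusted p = 0.0012) were higher too. ER stress (5 of 17 lower, median -0.15, adjusted p = 0.0036) and the immature myeloid list (5 of 8, median -0.31, adjusted p = 0.0039) were lower. Marker lists of other cell types did not pass: fibroblast, which holds FAP (1 of 3 higher and 1 lower, adjusted p = 0.47), epithelial (2 of 3 lower, adjusted p = 0.18) and lymphocyte (1 of 6 higher, adjusted p = 0.7). The AhR target list did not shift (1 of 7 lower, median -0.08, adjusted p = 0.79). Preparation day is a property of the plate, and the 6 plates allow 10 splits, too few for a share under 0.05; the real split gave 3144 genes and the highest of the others 319. Preparation day and the plates handled on it are confounded, and the exposure effects in the report are differences within a plate.

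A hypothesis is that cell cycle genes rose in the mean response because a larger share of cells had stayed undifferentiated. The immature myeloid list had a median of 0.11 against 0.16 for the cell cycle list, and the macrophage list did not shift (median -0.01, adjusted p = 0.37), so that such a share and a change within macrophages cannot be told apart. The technical axis is argued against as the whole cause, since with it as a covariate the cell cycle list still rose (camera, adjusted p = 7.9e-15). The axis was taken from the residuals of the same samples, so the size of that p is partly built in.

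A further hypothesis is that the materials differ in the size of one response. Over the 7 materials at IC20 the mean effect on the AhR list and that on the cell cycle list had Pearson's r of -0.97 (exact permutation p = 6e-04, adjusted over 3 relations 0.0018) and Spearman's rho of -0.96 (exact permutation p = 0.0028, adjusted 0.0084), and r was -0.92 without CHT and SIG. With each score taken from separate samples r was -0.89 and -0.88, and with the technical axis as a covariate -0.91. For these 2 lists this is consistent with a response of graded size. It does not extend to all genes: HSPA1A and GPNMB rose with CHT (0.97 and 0.93) and not with SIG (-0.14 and -0.14). Their effects differed over the 7 materials also with the technical axis as a covariate (adjusted p = 0.0029 and 0.02), while CHT was not tested against SIG alone. Across genes, which are not independent replicates, the effects of 2 materials correlated at a median of 0.17, from -0.22 (CHT and SIG) to 0.46 (NM400 and SIG), and with the technical axis as a covariate these pairs correlated at 0.42 and 0.23. Preparation days held 3, 3 and 1 materials, too few for a relation within a day.

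Whether a larger mass concentration gives a larger fall of AhR targets was also tested. The AhR score and log2 mass concentration had Pearson's r of -0.75 (exact permutation p = 0.051, adjusted 0.051) and rho of -0.70 (exact permutation p = 0.1, adjusted 0.1), and r was -0.29 without CHT and SES. The test did not pass, and the relation cannot be told apart from that of these 2 materials. The cell cycle score and mass concentration had r of 0.77 (exact permutation p = 0.044, adjusted 0.051) and rho of 0.78 (exact permutation p = 0.052, adjusted 0.078), and r was 0.3 without CHT and SES.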
